A study of Homo sapiens with 10 samples.

How the data were processed

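Total RNA from Caco-2 cells was measured on 10 single-channel oligonucleotide arrays, 5 from control cells and 5 from cells given vitamin D, with 24 h of exposure per the labels. The sample titles number 5 experiments and give each number to 1 control array and 1 vitamin D array. They do not say whether the experiments were separate cultures. P-values of single probe sets therefore measure the spread between these numbered experiments, which may be partly technical. The compound, its dose and the vehicle were not given in the sources used here.

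The table holds the authors' deposited intensity for 12625 probe sets on a linear scale, with probe set names of the Affymetrix form. The software, the background correction and the scaling were not given in the sources used here. The deposited values themselves showed 2 properties. Of the 126250 values, 24.8% lay below 0, as a measure that subtracts mismatch or background brightness gives. The mean of each array without the lowest and highest 2% of its values differed from the median over arrays by at most 0.00955%, so the arrays had already been scaled to a common level. They were therefore used as deposited, under a rule that allowed deviations up to 10%. Scaling of this kind removes any overall rise or fall of RNA per cell, and values near or below 0 carry no usable ratio. All columns of the table matched a sample, and no pair of columns was identical. For arrays, their number limits the precision.

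Intensities below a floor were raised to the floor, and log2 was taken. The plan set the floor at the 20th percentile of all values or, if that was not above 0, at the next multiple of 5 percent. The 20th percentile was -132, so the 25th percentile, an intensity of 6.3, was used. A log2 change of a dim probe set depends on that floor. The 67 control probe sets were left out, and a probe set was tested if its mean log2 value lay at or above the 40th percentile, which left 7535 of 12558. Gene names came from the platform annotation, with symbols checked through Entrez identifiers: 10943 probe sets had 1 gene, 545 had several and 1070 had none listed. Of the first kind, 10934 matched and 0 symbols needed an update. The tested probe sets covered 5498 distinct genes. No genome build is named for the array, and no coordinates are given.

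Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 10 arrays, no covariate), with Benjamini-Hochberg adjustment over tested probe sets and a threshold of 0.05. The same fit with the experiment number as a block was the alternative. The titles put same-numbered arrays in a shared experiment, so the numbers were treated as pairs on the basis of the labels. The correlation of deviations from the group means between same-numbered arrays was 0.186, 0.150, 0.0995, 0.0307 and 0.0535 for experiments 1 to 5. Gene lists, 27 in number, were tested with camera on 1 probe set per gene, the brightest. It used a preset inter-gene correlation of 0.01 and adjustment over the 27 lists. Camera compares a list's genes with the other genes. With the preset correlation its p-values therefore rest largely on the spread between genes, not between experiments. Camera with an estimated correlation and fry were run beside this test. A list's shift is the mean log2 change of its members minus that of all tested genes, in each experiment. Single values and list shifts were compared by an exact two-sided permutation test over the 252 assignments of 10 arrays to groups of 5. This test cannot give a p below 0.00794. Agreement between experiments was described by Pearson's r across probe sets, which are not independent replicates, with no p-value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

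Genes were named by a rule. If fewer than 10 probe sets passed, the 12 highest and 12 lowest by limma's moderated t were named as ranked, not as changed, with up to 8 each way from the fit with the block. CYP24A1, VDR, TRPV6, CYP3A4 and ABCB1 were named whenever measured. Up to 4 members with the smallest p were named per list. Probe sets with no gene or several genes were counted, not named. This rule, the lists, the tests and the first set of alternatives were fixed before the data were examined. The exact permutation tests on the 5 genes named in advance and on the lists were chosen after seeing the data. So were the lists followed through the alternatives, the bound for dim probe sets and the added alternatives.

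The procedure was tested on simulated data for this comparison, with 7535 probe sets, 20 runs and 200 changed probe sets per run. It recovered 51.9% of probe sets changed 2-fold, 77.5% of those changed 4-fold and 87.7% of those changed 8-fold, with a false share of 5.03%. With 200 changed probe sets per run the adjustment is less strict than where few change, and no differences between experiments were simulated. These shares therefore do not give the power of the real comparison. For lists, a simulated log2 shift of -0.25 in the mitosis list was called in 20 of 20 runs, with 0.15 other lists called per run. The simulated probe sets varied independently of each other, so the run does not test how camera behaves with correlated genes. In the real arrays, other drawn splits into groups of 5 called a median of 2 lists. Alternatives covered the normalization, the floor, the filter on dim probe sets, the variance model, the pairing, the choice of probe set per gene and the list test, and each experiment and each array was left out in turn.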

Results

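Caco-2 is a human colon carcinoma line that can take on features of absorptive cells of the small intestine, and the series asks how vitamin D alters its gene expression. RNA was profiled on 10 arrays from 5 numbered experiments, each with 1 control array and 1 array of cells given vitamin D for 24 h. Median intensity was 849 ± 42.7 (SD, n = 5) on the control arrays and 867 ± 28.0 (SD, n = 5) on the vitamin D arrays. The share of values below 0 had an SD of 1.30 and 1.71 percentage points in the 2 groups and reached 27.5% on vitamin D array 5. The ratio of 3' to 5' signal of GAPDH, a measure of RNA integrity, was 1.45 ± 0.107 in controls and 1.39 ± 0.136 with vitamin D. Log2 values of pairs of arrays correlated at r between 0.708 and 0.870 across probe sets. The arrays with the lowest mean r to the others were vitamin D 5 (0.766), vitamin D 1 (0.770) and control 1 (0.792).

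The comparison of vitamin D with control cells asks which transcripts differ after exposure. The widest gap among the genes named in advance was that of CYP24A1, which encodes the hydroxylase that inactivates the vitamin D hormone and is a classical target of its receptor. Its intensity was -107 ± 125 (SD, n = 5) in control cells, with no array above 88.6, and 3853 ± 2158 (SD, n = 5) with vitamin D, from 1177 to 6452.5. It was higher with vitamin D in 5 of 5 experiments, and the groups did not overlap. TRPV6, the apical calcium channel of intestinal cells, read -193 ± 357 in controls and 715 ± 539 with vitamin D (SD, n = 5 each), higher in 5 of 5 experiments, although in experiment 2 both values lay below 0 (-195 and -48.4). A probe set of CYP3A4, a drug-oxidising enzyme, read 376 ± 82.9 and 886 ± 511, higher in 4 of 5 experiments.

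By the exact permutation test, p was 0.00794 for CYP24A1, the smallest this design can give, and 0.0159 for TRPV6. Adjusted over the 10 probe sets of the 5 genes, both exact values became 0.0794. With the arrays paired by experiment, the exact sign-flip p was 0.0625 for either gene, the smallest that 5 pairs can give. The CYP3A4 probe set had an exact p of 0.0794, or 0.265 after adjustment, and its other 2 probe sets had means below 0 in both groups. ABCB1, the efflux pump, read 307 ± 211 in controls and 619 ± 385 with vitamin D (SD, n = 5 each) on its brighter probe set, with an exact p of 0.175. For VDR, the vitamin D receptor itself, the 3 probe sets gave exact p values of 0.452, 0.675 and 0.738. CYP24A1 and TRPV6 lay below the filter on dim probe sets and had no place among the tested probe sets. For each gene 4 control arrays lay at the floor, which lowers the mean log2 even where the vitamin D arrays are bright. Counts among tested probe sets do not cover genes left out in this way. Without that filter, limma put CYP24A1 at an adjusted p of 0.0435, with a log2 change of 8.26 (SE 0.85) that depends on the floor. With the floor at the 40th percentile its log2 change was 2.90 (SE 0.39) at an adjusted p of 0.114 by limma.

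**Figure D1:**
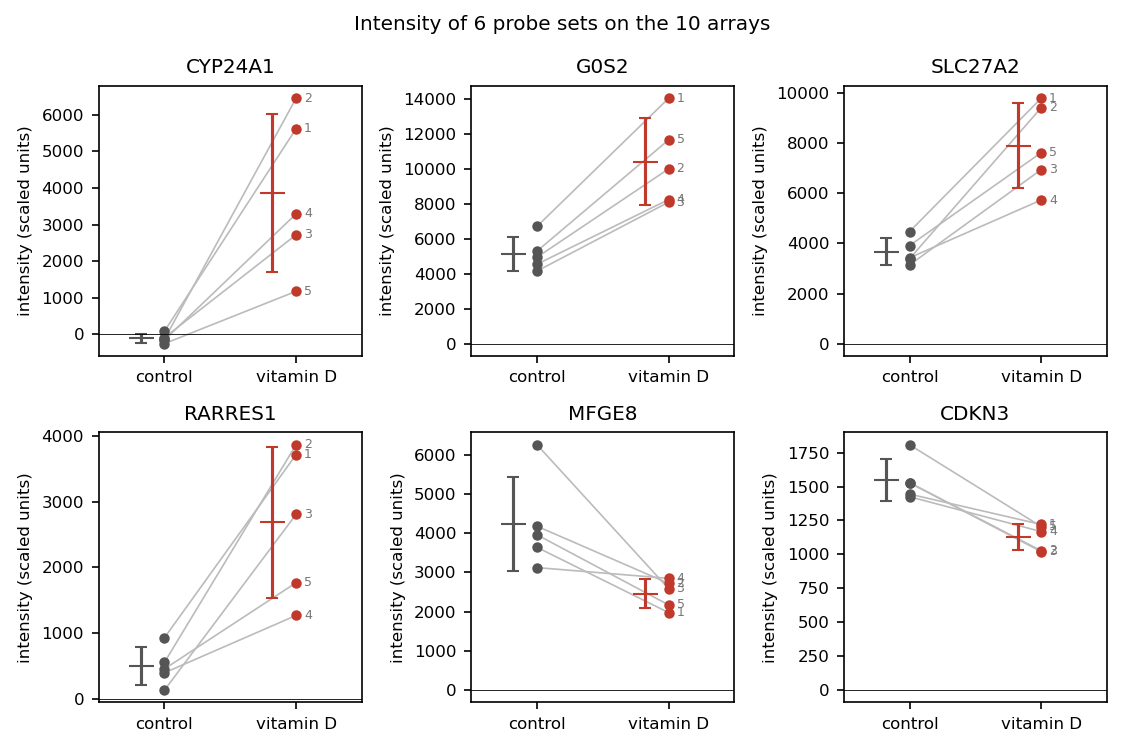
Intensity (scaled units) of 6 probe sets in control and vitamin D cells, as the 10 arrays, with lines joining arrays of the same numbered experiment and bars for the mean ± SD (n = 5). CYP24A1 lies at or below 88.6 in every control and at or above 1177 in every vitamin D array.

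Among tested probe sets, the highest ranked with vitamin D were those of SLC27A2, MET and SRI. SLC27A2, a very long-chain fatty acid transporter and acyl-CoA synthetase, read 3669 ± 530.0 in controls and 7900.5 ± 1700.5 with vitamin D, a log2 difference of 1.09 (SE 0.17). MET, the hepatocyte growth factor receptor, differed by 0.71 (SE 0.12), and 2 further tested probe sets of MET differed by 0.65 and 0.41. SRI, the calcium-binding protein sorcin, differed by 1.38 (SE 0.25). G0S2, an inhibitor of fat breakdown, read 5132 ± 981 and 10412 ± 2498, a difference of 1.01 (SE 0.19). CA12, a carbonic anhydrase, differed by 1.84 (SE 0.35) and by 0.87 on its brighter probe set. RARRES1, first described as a retinoid-responsive gene, differed by 2.54 (SE 0.51) and by 1.89 on another probe set. ATP6V1C1, XCL2, PPM1F, CEP250 and SLC20A1 followed with log2 differences of 1.94, 0.61, 0.72, 1.01 and 0.53. ATP6V1C1 was dim in controls, and its difference was 0.64 with the floor at the 40th percentile. Each of these 11 genes was higher in 5 of 5 experiments on the named probe set. Ranking by t on the same arrays favours such genes, so this adds no separate support. SLC16A5 differed by 2.03 (SE 0.48) on a probe set higher in 4 of 5 experiments, while its other 2 probe sets differed by -0.05 and 0.04. Ranked with the experiment as a block, COL7A1 at 1.01 and PSPH at 1.05 joined them.

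The lowest ranked were TXNDC9, at a log2 difference of -0.76 (SE 0.18), and CDKN3, a phosphatase acting on cyclin-dependent kinases, at -0.45 (SE 0.11). CDKN3 read 1546.5 ± 153 in controls and 1128 ± 97.3 with vitamin D. MKNK1, a kinase of the translation factor eIF4E, stood at -1.05 (SE 0.27), and MFGE8, a secreted protein that bridges dying cells to phagocytes, at -0.75 (SE 0.19). HMGB2, a chromatin protein abundant in dividing cells, stood at -0.45 (SE 0.14), and FSTL3, which binds activin, at -1.01 (SE 0.31). The chemokine CXCL5 stood at -0.61 (SE 0.19), TRIB2 at -0.69 (SE 0.22) and ANG, the ribonuclease angiogenin, at -0.79 (SE 0.25). These 9 were lower in 5 of 5 experiments, which the ranking favours in the same way. SUMO4, LRRC23 and NPHP4 stood at -0.48, -0.51 and -1.49 and were lower in 4 of 5. Other probe sets of LRRC23 gave -0.15 and 0.38. Ranked with the block, ANAPC15, N4BP2L2, ABCA1 and NFRKB joined, at -0.95, -0.93, -0.81 and -0.55, and other tested probe sets of N4BP2L2, ABCA1 and NFRKB lay between -0.14 and 0.09.

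None of these ranked genes passed with or without the experiment as a block. With limma, 0 of 7535 probe sets had an adjusted p under 0.05, the smallest being 0.397, and 221 had an unadjusted p under 0.05, of which 148 were higher and 73 lower, where chance gives 376.75. The excess of higher ones depended on the scaling, with 116 higher and 99 lower after scaling to a common median. With the experiment as a block the count was also 0, with 279 at an unadjusted p under 0.05. In a fit chosen after seeing the data, with the block and trend and robust variances, limma put 1 gene past the threshold, G0S2, at an adjusted p of 0.0339. Without the filter on dim probe sets, 3 of 12558 passed, all higher with vitamin D. These were CYP24A1 and 2 probe sets with no gene listed, whose highest intensities were 309 and 559.5.

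**Figure D2:**
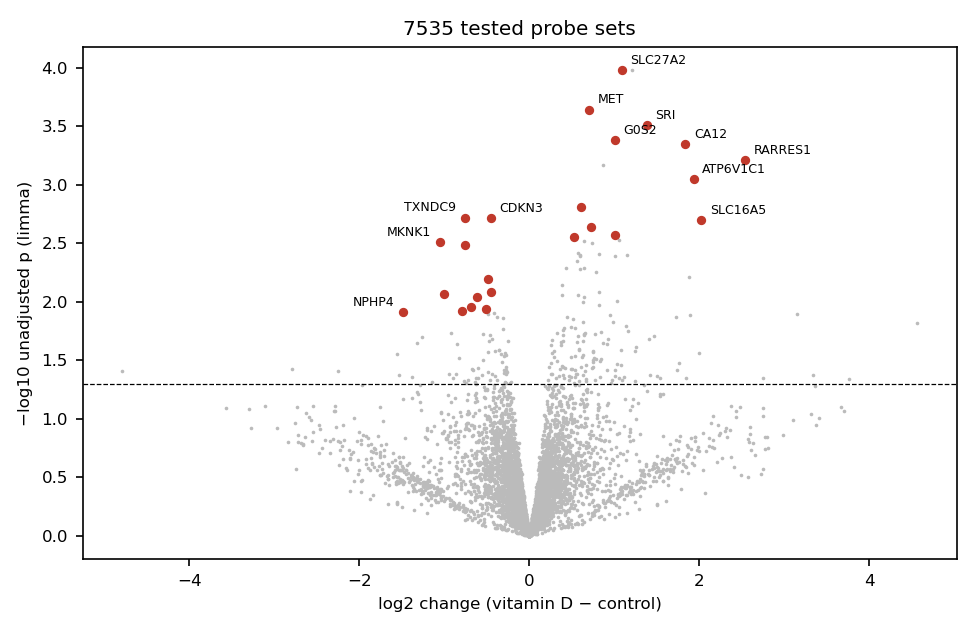
Log2 change (vitamin D minus control) against -log10 of limma's unadjusted p for the 7535 tested probe sets, with the ranked genes in red and a dashed line at an unadjusted p of 0.05. No probe set passed after adjustment, and 221 lie above the line.

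Genes of DNA replication and mitosis stood lower with vitamin D as groups. Of 33 tested genes of DNA replication and S phase, 29 were lower and 4 higher. RFC3, a subunit of the clamp loader, stood at a log2 difference of -0.55 (SE 0.22), GINS1 at -0.29 (SE 0.12), the thymidylate synthase TYMS at -0.25 (SE 0.12) and RPA3 at -0.27 (SE 0.14). Relative to all tested genes the list shifted by -0.26 ± 0.17 (SD over 5 experiments) and was lower in 5 of 5, though close to 0 in experiment 3. The median was -0.15, and much of the mean came from RRM2, RFC2 and POLE, dim genes at -1.82, -1.58 and -1.04 that stood at -0.62, -0.30 and -0.06 with the floor at the 40th percentile. Of 31 mitosis genes, 26 were lower, among them the securin PTTG1 at -0.38 (SE 0.13), the spindle checkpoint kinase TTK at -0.56 (SE 0.24), the motor KIF11 at -0.38 (SE 0.24) and BUB1B at -0.33 (SE 0.21). The mitosis list shifted by -0.18 ± 0.15 and was lower in 5 of 5 experiments, though close to 0 in experiments 1 and 4 (-0.036 and -0.033).

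Camera with its preset correlation called both lists lower, each at an adjusted p of 0.000941. Neither call held with an estimated correlation: for replication, adjusted p = 0.263 with an estimated correlation, and for mitosis, adjusted p = 0.347 with an estimated correlation. In either list 0 members passed over all genes and 0 when adjusted over the list alone, with 2 members of each at an unadjusted p under 0.05 by limma.

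Camera called 3 lists higher. Among 19 tested classical vitamin D receptor targets, 14 were higher and 5 lower, with a median log2 difference of 0.20. G0S2, GADD45A at 0.26 (SE 0.11), CYP3A4 at 1.03 (SE 0.42) and the calcium pump ATP2B1 at 0.47 (SE 0.20) had the smallest p. Over all genes 0 passed, and 1 passed when adjusted over the list alone, G0S2, at an adjusted p of 0.00790 by limma. The list was called at an adjusted p of 0.0304, a call that was lost at adjusted p = 0.263 with an estimated correlation. Its shift was above 0 in 3 of 5 experiments. CYP24A1 and TRPV6, held below the filter by controls at the floor, did not enter it.

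Of 39 genes of oxidative phosphorylation, 33 were higher, by small amounts: the median difference was 0.08, with CYCS, cytochrome c, at 0.26 (SE 0.11), ATP5MC1 at 0.32 (SE 0.16), COX5A at 0.21 (SE 0.12) and COX6B1 at 0.19 (SE 0.12). The camera adjusted p was 0.00732, and the call was lost at adjusted p = 0.595 with an estimated correlation. Over all genes 0 passed, and 0 when adjusted over the list alone. Of 31 genes of hypoxia and glycolysis, 24 were higher, with a median of 0.06, and the list's shift was above 0 in 3 of 5 experiments. CA12 stood at 0.87 (SE 0.18), PDK3 at 1.18 (SE 0.61), PFKP at 0.53 (SE 0.29) and GPI, a glycolytic isomerase, at 0.25 (SE 0.16). PDK3 was dim in both groups and stood at 0.07 with the floor at the 40th percentile. Over all genes 0 passed, and 1 when adjusted over the list alone, CA12, at an adjusted p of 0.0210 by limma, or 0.0771 with the experiment as a block. The camera adjusted p was 0.0494, and this call too was lost at adjusted p = 0.595 with an estimated correlation. Without experiment 1 and vitamin D array 5, a setting chosen after seeing the data, the list turned lower.

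**Figure D3:**
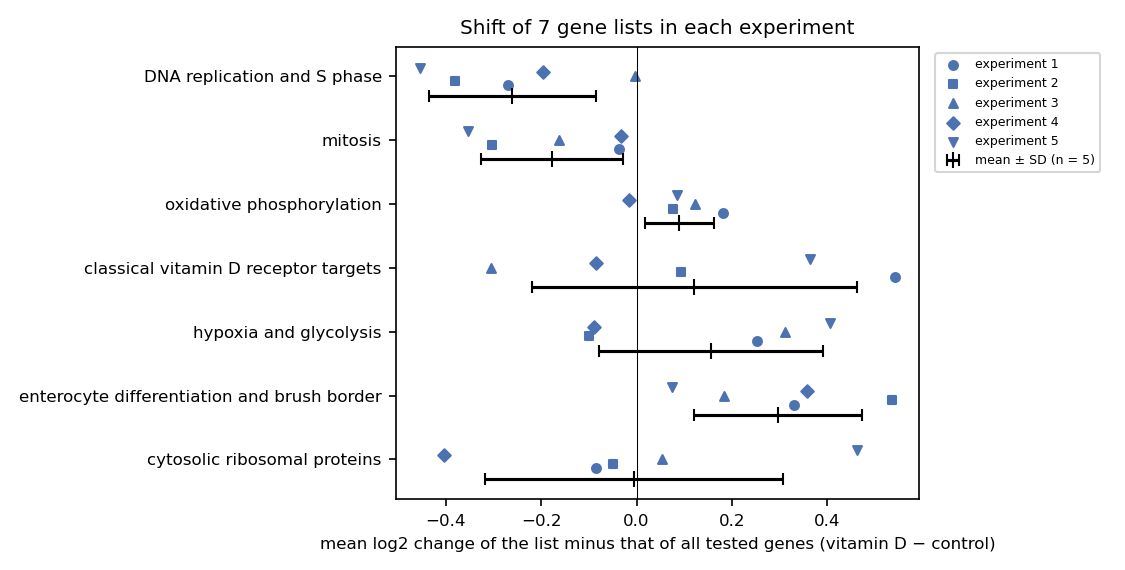
Shift of 7 gene lists in each of the 5 experiments: the mean log2 change of the list's genes minus that of all tested genes, vitamin D minus control, with bars for the mean ± SD (n = 5). DNA replication and mitosis lie below 0 in 5 of 5 experiments and the enterocyte list above 0 in 5 of 5, while cytosolic ribosomal proteins run from -0.40 to 0.46. Chance alone puts 6.25% of lists on 1 side of 0 in 5 of 5, and the fibroblast and stroma list, not drawn, also lay below 0 in 5 of 5.

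Markers of enterocyte differentiation and the brush border were not called, at an adjusted p of 0.201 by camera, although the list's mean shift was above 0 in 5 of 5 experiments (0.30 ± 0.18, SD). Its members went both ways, with 11 of 20 higher and a median of 0.03, and ALPI and CEACAM6 carried the mean. Intestinal alkaline phosphatase, ALPI, read 396 ± 673 in controls and 2316 ± 646 with vitamin D (SD, n = 5 each), a log2 difference of 4.56, or 1.82 with the floor at the 40th percentile. KLF5, a transcription factor of the intestinal epithelium, differed by 0.33 (SE 0.11) and CDX2, an intestinal transcription factor, by 0.24 (SE 0.13). CEACAM6, an adhesion molecule, read 5139 ± 4342 in controls and 10896.5 ± 4562 with vitamin D, higher in 5 of 5 experiments. Over all genes 0 passed by limma, and 0 when adjusted over the list alone, with 3 at an unadjusted p under 0.05. For calcium transport and buffering, 7 of 10 genes were higher, for drug and steroid metabolism 16 of 26, and for cyclin-dependent kinase inhibitors and growth arrest 10 of 17. Camera's adjusted p was 0.375, 0.251 and 0.773, and in each of these lists 0 passed over all genes and 0 when adjusted over the list alone. In drug and steroid metabolism, CYP2E1 differed by 0.77 (SE 0.27) and HSD17B2, which oxidises oestradiol and testosterone, by 0.49 (SE 0.23), each higher in 5 of 5 experiments, while GSTA4 stood at -0.25 (SE 0.13) and AKR1C3 at -0.21, each lower in 5 of 5.

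Of the 27 lists, camera with an estimated correlation called 0 and fry called 0, against 5 with the preset correlation. No list passed the exact permutation test of list shifts after adjustment over the 27, the smallest adjusted p being 0.643. With the experiment as a block, in a fit chosen after seeing the data, fry called 5: vitamin D receptor targets, DNA replication, mitosis, enterocyte differentiation, and cell junctions and adhesion, each at an adjusted p of 0.0445.

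The last comparison asks whether the 5 experiments ranked probe sets alike. Across the tested probe sets, the log2 differences of the 10 pairs of experiments correlated at a median r of -0.00676, from -0.0602 to 0.0730. The same direction in 5 of 5 experiments was seen for 479 probe sets, 243 higher and 236 lower, where chance gives 471. The control and vitamin D arrays did not overlap for 56 probe sets, or 0.743% of those tested, where chance gives 0.794%.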

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

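The tests of 1 experiment alone, of the chance division behind the replication list and of the block as a reason for few low p values were chosen only after the result was seen, and so were the added floors and the background bound for dim probe sets.

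Some probe sets below the filter had groups that did not overlap. CYP24A1 averaged 3853 with vitamin D against controls at or below 88.6. CLDN5, a tight junction protein, averaged 876 ± 179 (SD, n = 5) with vitamin D and -87.9 ± 308 in controls, higher in 5 of 5 experiments. Of 153 untested probe sets with a group mean above 629, the size of the 10th percentile of all values, 4 were of this kind. Chance gives no fixed share for them, since the group means that decide which probe sets enter depend on the difference itself. The others were JUNB, at -45.7 ± 257 in controls and 894 ± 598 with vitamin D, and LY86, at 832 ± 314 and 42.0 ± 111.

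In 7 of 92 groups, 1 array lay far from the other 4 relative to the group's range, and chance marks about 1 in 20 groups in this way. The share of values below 0 was 27.5% on vitamin D array 5 against 23.3% to 24.4% on the others, a gap of 0.735 of the range. ATP6V1C1 read 486.5 in control 1 against 104 to 199 (0.750), and CDKN3 read 1808 in control 5 against 1425 to 1528 (0.731). SUMO4 read 16740.4 in control 5 against 13959 to 14435.5 (0.829) and 14366.5 in vitamin D 2 against 9137 to 10487 (0.742). TRIB2 read 1811.5 in control 1 against 3057 to 3181 (0.909). COL7A1 read 2868 in vitamin D 3 against 1381 to 1804 (0.716).

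Chance cannot be excluded as the source of the list count. Among 100 splits of the 10 arrays into groups of 5, the real one included, 100 gave at least as many probe sets past the threshold as the real 0, the highest other being 2, which any split would do against a count of 0 and so says nothing about chance. For gene lists, 10 of the 100 splits called as many as the real 5, the highest other being 9. Of the 16 splits that part all 5 pairs, too few for a share under 0.05, the highest other called 4 lists. The highest number at an unadjusted p under 0.05 in any split was 800, in one that kept both arrays of experiment 1 together, and 411 among the others that part all pairs, against the real 221.

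For the DNA replication and mitosis lists, camera's calls with the preset correlation stayed with array brightness or RNA integrity as a covariate. An estimated correlation removes them without any covariate (adjusted p 0.263 and 0.347). With the spike-in level or the GAPDH ratio as a covariate, camera's adjusted p was 0.000926 and 0.000844 for replication, and 0.000926 and 0.00932 for mitosis. Neither measure differed between groups beyond its spread. The spike-in level was 37127 ± 12503 in controls and 36981 ± 16433 with vitamin D, the ratio 1.45 ± 0.107 and 1.39 ± 0.136 (SD, n = 5 each). Covariates so balanced could hardly remove calls that rest largely on the spread between genes, so keeping the calls decides little about either cause. Leaving out each experiment in turn gave replication shifts no higher than -0.21, which follows from shifts below 0 in all 5 and tests nothing further. Chance division of the arrays stays open. A joint shift of both lists had an exact permutation p of 0.0238 over assignments that ignore the pairs. By that test replication alone had a p of 0.0317 and mitosis 0.0714, or 0.643 for each after adjustment over the 27 lists. Paired by experiment, each list alone had an exact sign-flip p of 0.0625. The 2 lists had been picked as the first of 27, and a test over all lists replaced the joint one after its p was seen. In 60 of 100 splits some list had a camera p as small, most often cytosolic ribosomal proteins, while replication itself had a p as small as the real 3.99e-05 in 1 of 100, the real split, and nearly so (4.09e-05 and 4.48e-05) where 4 of the 5 controls stayed together with vitamin D 4.

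Fewer probe sets than the nominal number had an unadjusted p under 0.05 (221 against 376.75, or 2.93% of those tested). The shortfall is against that nominal number, not against other divisions of these arrays. The share stayed below 5% with the experiment as a block (3.70%), without the arrays that stand apart (3.38%) and among 5583 probe sets with all 10 intensities above the 40th percentile (3.24%). The tables argue against those arrays as the whole reason; the block and a higher floor together narrowed or removed the shortfall at some floors, with 337, 357, 372 and 361 at the 30th, 35th, 40th and 50th percentiles and 390 at an intensity of 1000, or 377, 389, 395, 364 and 330 with trend and robust variances, but not at the highest floor tried (262 and 322 against 627.9). Thus differences between experiments and values near the floor stay open as joint reasons. The other splits that part all pairs had a median of 203, and 6 of the 16, the real one included, reached the real count. All other drawn splits had a median of 265. Low counts thus also arise when the arrays are divided without regard to vitamin D, and no biological explanation was tested.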

How the results depend on the processing

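The further floors, the generalised log, the combined settings and the joint omission of experiment 1 and vitamin D array 5 were chosen only after the result was seen. Limma's count of 0 probe sets held with the replicate block (0), quantile normalization, a common median, the floor at the 40th percentile, the pseudocount, the stricter filter, trend and robust variances, a random block, 1 probe set per gene, the generalised log and every omission of an experiment or array, with 174 to 330 at an unadjusted p under 0.05 over the omissions. Without the filter it was 3. Among added floors it was 1 at the 30th percentile and 2 at the 35th, CYP24A1 both times with CLDN5 in the latter, and 0 at the 50th percentile and at 2 fixed intensities above it. Combined with trend and robust variances it was 1 at the 30th, 35th and 40th percentiles, 0 at the 50th and the lower fixed intensity, and 2 at the higher. With the block added to those it was 1 at the 25th, 35th, 40th and 50th percentiles and at the lower fixed intensity, 2 at the 30th, G0S2 each time, and 25 (20 higher, 5 lower) at the higher, whose ties let all 12558 probe sets be tested; the block without trend gave 0 at each floor. Lists called ranged from 2 to 6 over omissions against 5: 2 without experiment 1, vitamin D array 1, control 3 or control 5, and 3 without experiment 2, control 1, vitamin D 2 or vitamin D 4, or without experiment 3 with the block. Without experiment 1 and vitamin D array 5 together, 3 lists were called, replication was not, and hypoxia and glycolysis turned lower (0.954). The block left the count at 5 with camera, and the other changes of normalization, floor or filter gave 4 to 7. An estimated correlation gave 0 with either floor, filter or block. Fry gave 0 without the filter at either floor, 1 at the 40th percentile with or without block, 1 with no filter and block, and 3 with no filter, block and the 40th percentile. Over 35 settings, which leave out fry and the estimated correlation combined with another floor, filter or block, replication was called in 32, mitosis in 33, oxidative phosphorylation in 23, vitamin D receptor targets in 21, hypoxia and glycolysis in 14, the enterocyte list in 0 and Wnt targets in 1. Apart from the estimated correlation and fry, these settings all used camera with the preset correlation, and 20 were overlapping omissions. The tally therefore cannot show that the calls hold under another list test. A VDR probe set at -1.36 stood at 0.27 with the floor at the 40th percentile, with or without block or a filter on linear intensity; another VDR probe set at -0.72 stood at 0.01 there, below the filter. The other 1124 values of tested named probe sets kept their direction. Median agreement between experiments was -0.00624 with quantile normalization, -0.0113 without the filter and -0.00920 with the stricter one. Apart from fewer arrays in the omissions, the cause was not tested. The floor at the 10th percentile (-629) has no log and was not run, nor was a random block for lists. The pseudocount was the 25th percentile, since the 20th was below 0. Trend and 1 probe set per gene do not enter camera and could not move its count. Intensities near background limit ratios of genes that are dim in a group, such as CYP24A1 in controls.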

Other observations

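The tests on further probe sets of a gene were planned before their result was seen, while the remarks on single lists were chosen after.

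Several gene groups outside the lists called by camera held members with the same direction in every experiment, which 6.36% of all tested probe sets had, where chance gives 6.25%. Among Wnt and beta-catenin targets, 17 of 22 were higher, with the receptor kinase EPHB4 at a log2 difference of 0.60 (SE 0.16) and ENC1 at 0.25 (SE 0.12) in 5 of 5 experiments, while BMP4 stood at -0.86 (SE 0.36) (list adjusted p 0.201 by camera). Among NF-kB and inflammatory mediators, 10 of 17 were higher, with a median of 0.16 and RELB at 0.28 (SE 0.24) in 5 of 5, while CXCL5 and the acute-phase gene SAA1 (-0.85, SE 0.31, or -0.40 with the floor at the 40th percentile) were lower in 5 of 5, and CXCL5 was the 1 gene that passed adjusted over the list alone with the experiment as a block. The RNA-binding protein ZFP36, which destabilises cytokine transcripts, stood at 0.40 (SE 0.14) in the immediate early list (0.360), and RARB, a retinoic acid receptor, at 0.58 (SE 0.22), higher in 4 of 5, among nuclear receptors (0.923). Cholesterol synthesis genes were lower in 14 of 18, with FDPS at -0.19 (SE 0.17) in 5 of 5 experiments (0.289). None of these groups had a member that passed over all genes, and none had any adjusted over the list alone without the block.

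Lists of other cell types gave no call by camera: goblet, enteroendocrine and Paneth cells (adjusted p 0.327), fibroblast and stroma (0.585), hepatocyte (0.847) and leukocyte (0.923). The fibroblast and stroma list was lower in 5 of 5 experiments, with a mean shift of -0.53 ± 0.26 (SD), but its median was -0.08 and PDGFRB, at -2.72 or at -0.58 with the floor at the 40th percentile, carried most of the mean of 6 genes. Hepatocyte genes such as albumin were bright in both groups, ALB at 58404 ± 11964 in controls and 52868 ± 7683 with vitamin D (SD, n = 5 each). The p53 and apoptosis list (0.327), unfolded protein response (0.387), growth factor signalling (0.610), lipoprotein and fatty acid metabolism (0.676), interferon response (0.773), cell junctions (0.773), ribosomal proteins (0.775), metallothioneins and oxidative stress (0.824), NF-kB (0.923) and heat shock (0.923) were not called either. Mean and test differed in sign for the NF-kB, nuclear receptor, heat shock, leukocyte and hepatocyte lists, and median and mean for the interferon, hepatocyte and NF-kB lists.

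Cytosolic ribosomal proteins lay apart from all tested genes in 2 experiments, by 0.46 in experiment 5 and -0.40 in experiment 4, and close to them in experiments 1 to 3 (-0.08, -0.05 and 0.05), with a mean of -0.01 ± 0.31 (SD, n = 5).

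Where a gene had several tested probe sets and the strongest had an unadjusted p under 0.05 by limma, 36 of 64 further probe sets (56.25%, exact 95% interval 43.3% to 68.6%) went the same way. That interval treats the further probe sets as independent, although genes such as MET gave several on the same arrays. It spans 50%, so these data cannot tell whether such differences belong to the gene's RNA. A share as large arose in 65 of 100 splits of the arrays. The other drawn splits had a median of 58.2% and reached 70.8%. Thus 50% is not the level that other divisions give, and chance cannot be excluded.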
